A study of Mus musculus with 10 samples.

How the data were processed

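RNA was isolated from mouse placentas at embryonic day 15.5 and sequenced as Illumina libraries, 1 library per placenta, with 5 wild-type and 5 Zfp36l3 knockout biological replicates per the labels. The authors deposited a single table of FPKM values, given to 3 decimals for 28886 RefSeq transcript accessions and 1 column per library. Reads had been aligned with BWA to the mouse genome build mm10, per the submitters' processing notes. The versions, the program that counted reads, the annotation release, the treatment of reads shared between isoforms or gene copies, the strand setting and the strain background were not given in the sources used here. FPKM divides by transcript length and by library total, so a few abundant transcripts can shift all others, and a bias against short fragments appears as a change of short transcripts. Columns were assigned to libraries by the names in the labels, replicates were numbered in accession order, which pairs nothing, and no column was left without a sample.

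Where a symbol had several accessions, which was so for 4698 of 20290 symbols, the accession with the highest mean over all 10 libraries stood for the gene. Genes with a mean of at least 1 FPKM were tested (10078). Values were transformed to log2(FPKM + 1), with a pseudocount of 1, and knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust options off, two-sided, genotype as the only term). Benjamini-Hochberg adjusted p below 0.05 counted as a call, and every adjusted p of a single gene comes from this fit unless another is named. FPKM are not counts, so no count model was used. Library-level scores are the mean over a list's genes of log2(FPKM + 1) minus the gene's mean over the 10 libraries, and were compared by exact permutation of the 10 libraries into 5 and 5, with p adjusted (Benjamini-Hochberg) over the 25 scores compared. Descriptive steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

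Depth was not given as counts. For whole reads, FPKM times transcript length moves in steps of the value of 1 read, so the step that best divided the low values gave an estimate of each library's reads, from 31.0 to 64.5 M. Transcript lengths came from the GENCODE annotation of the mm10 assembly, matched by accession for 19824 symbols. On average 64.5% of low values, those of at most 8 reads, lay within 0.1 of a whole number of reads, so the depths are estimates and no counts were recovered from them. A gene at 1 FPKM rests on fewer reads in the 3 libraries under 40 M reads than in the other 7.

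Before the data were examined, 24 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The lists cover the TTP family, iron uptake, storage and export, transcripts with an iron-responsive element, reported AU-rich targets of TTP-family proteins, syncytiotrophoblast and labyrinth trophoblast, spongiotrophoblast and glycogen trophoblast, trophoblast giant cells, the placental prolactin family, fetal endothelium, erythroid cells, yolk sac endoderm, maternal decidua and uterine stroma, uterine natural killer cells, macrophages and granulocytes, labyrinth mesenchyme and pericytes, cholesterol synthesis and SREBP2 targets, hypoxia response, cell division, amino acid, glucose and lipid transport, imprinted genes, unfolded protein and integrated stress response, interferon response, the mitochondrial respiratory chain and Y-linked genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance and compares them with no other genes. Calls were also counted with p adjusted over the list alone. Lists overlap in some members, and placental tissue itself expresses many genes of the lists for other cell types.

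The genes named were the 4 of the TTP family, the 12 called genes with the highest and the 12 with the lowest log2 fold change, the 5 called genes with the largest rise and the 5 with the largest fall in mean FPKM, the members of both iron lists and of the AU-rich list, and up to 4 tested members of each other list with the smallest p. Predicted genes without a proper name were counted and not described. Snap91, Irf9, Slc38a2, Slc7a1, Lpl, Mfsd2a and, in the closing section, Snurf, Mt1, Srxn1, Firre, Casd1, Ppp1r9a, Erbb3, Errfi1, Gclm, Gclc, Txnrd1 and the genes next to Zfp36l3 were named after their values were seen. The rule took 141 genes, of which a subset is described. A gene was marked uncertain where at least 20% of the 50-base words of its transcript occurred in transcripts of another gene, which applied to 17 of the 141; for Peg10 and for genes outside the rule this search was not made.

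For the motif, annotated 3' UTRs of the GENCODE annotation were searched for TATTTAT in the 9838 tested genes that had one (97.6%). Called and uncalled genes were compared by Fisher's exact test and by logistic regression with log2 length of the longest 3' UTR, and 20 shuffled heptamers of the same base composition served as controls. Coordinates are on mm10 and 1-based. Those of motif sites come from that annotation, and the intervals of genes from RefSeq gene records.

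Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median-of-ratios rescaling, quantile normalization, a trend and robust prior, limma's array weights, the level of Y-linked genes as a covariate, an exact rank-sum test, and each library left out in turn. Added after seeing the data were a per-library loess correction for transcript length and GC content (span 0.3), the 7 libraries above 40 M reads alone, the other 9 pairs of wild-type libraries against the 5 knockouts, the mean over a gene's accessions, and leaving out transcripts under 500 nucleotides. The calls were also counted in 100 of the 126 ways of splitting the 10 libraries into 5 and 5. In the self-test on simulated data with known answers, on the 10078 genes of this comparison, 200 genes were changed in each of 5 simulations. The fit recovered 83.9% of those changed 1.5-fold, 94.6% at 2-fold and 100% at 4-fold, with 4.5% of calls false. The 200 genes were divided among these fold changes, which were set on the log2(FPKM + 1) scale. Each gene was drawn independently, without variation shared between genes or depth differences between libraries. These shares may therefore not hold in the real data.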

Results

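RNA sequencing measured transcript levels in mouse placentas at embryonic day 15.5, from 5 wild-type conceptuses and 5 conceptuses in which Zfp36l3 had been knocked out. Zfp36l3 encodes a member of the tristetraprolin (TTP) family, proteins with tandem zinc fingers that bind AU-rich elements in 3' untranslated regions (UTRs) and promote decay of the bound mRNA. The comparison asks which placental transcripts change level when this protein is lost. The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped total of the library) for 28886 RefSeq transcripts of 20290 gene symbols. Depth was estimated from the step between low FPKM values. Wild-type replicates 1 to 5 came to 56.8, 63.7, 31.0, 33.1 and 33.9 M reads, and knockout replicates 1 to 5 to 64.1, 64.5, 60.2, 45.7 and 61.3 M. The 3 shallower libraries, wild-type replicates 3 to 5, were all wild type, so no comparison of genotypes was possible among them. Whether they were sequenced as a separate batch was not stated; if so, that batch and genotype cannot be told apart in those 3 libraries. Pearson correlations of log2(FPKM + 1) between libraries across genes were 0.958 to 0.994 within groups and 0.942 to 0.988 between groups.

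Zfp36l3 transcript (NM_001009549, X:53772686-53776394 on the minus strand, mm10) was abundant in every wild-type placenta and listed at 0 in every knockout placenta. Wild-type replicates 1 to 5 had 38.3, 39.0, 35.4, 33.5 and 32.7 FPKM, and all 5 knockout libraries had 0 FPKM, so the target's level matched the genotype of each library. The fitted difference was −5.20 on the log2(FPKM + 1) scale (limma, adjusted p = 1.17e-13). The other 3 members of the TTP family did not pass the test. Zfp36, the gene of tristetraprolin itself, had 17.0 FPKM in wild type and 18.5 in knockout (log2 fold change 0.11, adjusted p = 0.309). Zfp36l1 had 11.6 and 13.8 FPKM (0.21, adjusted p = 0.48), and Zfp36l2 had 13.1 and 15.5 FPKM (0.24, adjusted p = 0.155). Over these 4 genes the median log2 fold change was 0.16 and the mean −1.16, a difference in sign set by Zfp36l3, and the list as a whole was not called (camera, down, adjusted p = 0.581). Adjusted over the list alone, Zfp36l3 was lower and 1 member was higher.

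Knockout placentas held less transferrin receptor mRNA and more mRNA of a growth factor, a lipase and a syncytin. Tfrc, which encodes the receptor for iron-loaded transferrin, fell 6.38-fold, from 258 ± 65.9 to 40.4 ± 31.2 FPKM (mean ± SD, n = 5 placentas per group; limma, adjusted p = 0.0018). Without knockout replicate 5, the highest of the knockouts, the fall in mean FPKM was 9.68-fold. Hbegf, the gene of heparin-binding EGF-like growth factor, rose 3.15-fold, from 10.8 ± 2.01 to 34.0 ± 2.94 FPKM (limma, n = 5, adjusted p = 5.26e-05). Lipg, which encodes endothelial lipase, rose 2.59-fold, from 34.2 ± 4.87 to 88.6 ± 8.05 FPKM (limma, n = 5, adjusted p = 5.26e-05). Syna, the gene of the fusogenic envelope protein syncytin-A, rose 2.11-fold, from 21.2 ± 3.66 to 44.8 ± 4.95 FPKM (limma, n = 5, adjusted p = 0.00135). All of these groups were separated without overlap. Most other changes were small. Among the 595 genes called, Zfp36l3 aside, the ratio of mean FPKM exceeded 1.5-fold in 164 and 2-fold in 42, with a median of 1.34-fold. On the log2(FPKM + 1) scale of the fit, 83 exceeded 1.5-fold and 16 exceeded 2-fold, with a median of 1.27-fold.

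**Figure D1:**
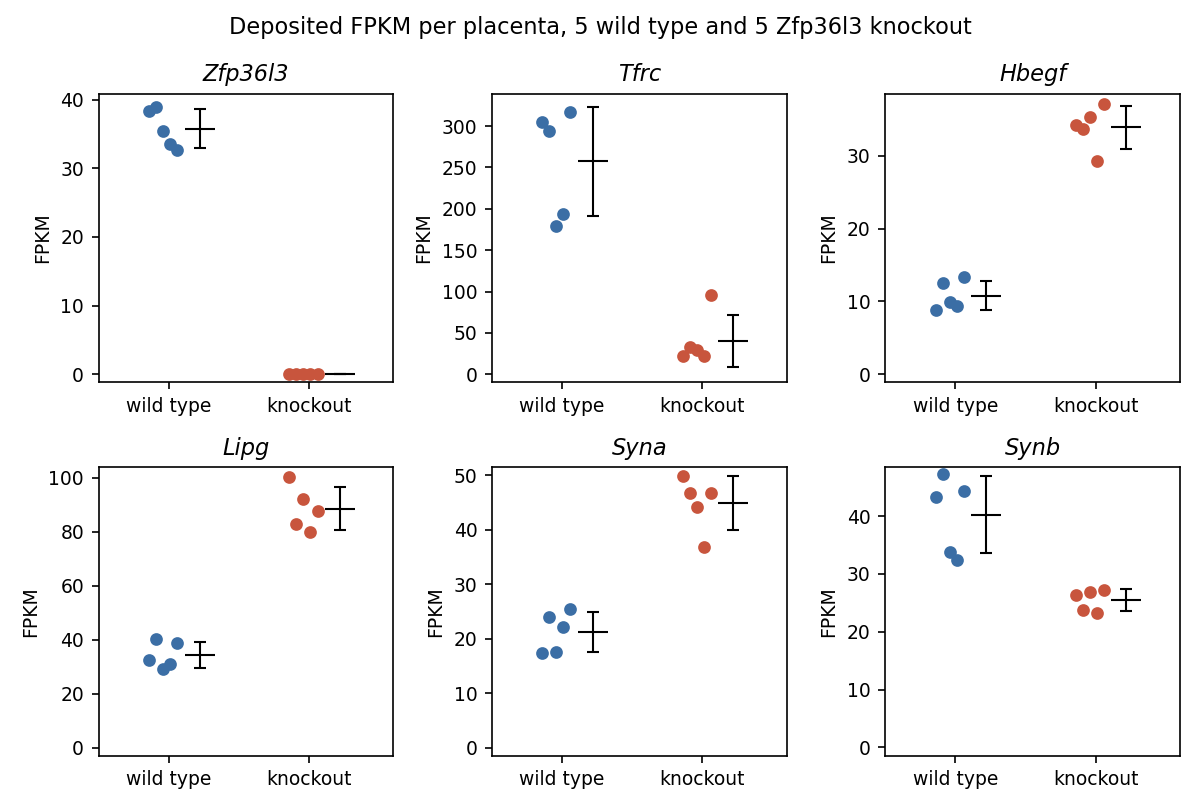
FPKM of 6 genes in each placenta (y axis; 1 point per library, 5 wild type and 5 Zfp36l3 knockout, with the group mean and SD as a bar). Zfp36l3 is at 0 FPKM in all 5 knockouts, and knockout replicate 5 lies at 95.7 FPKM of Tfrc against 22.4 to 32.5 in the other 4.

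Of 10078 genes with a mean of at least 1 FPKM, 595 passed limma's test at an adjusted p below 0.05, 305 of them higher and 290 lower in knockout placentas. Fold changes and their standard errors are on the log2(FPKM + 1) scale, which understates the change of low genes. The groups did not overlap in 809 genes, 8% of those tested, where chance alone gives 0.79%, and 518 of the 595 called genes were among them. Without the 3 shallower wild-type libraries, the remaining 7 gave 136 calls, 61 higher and 75 lower, which included 117 of the 595. Leaving out 1 library lowered the count to 282 (wild-type replicate 2), 290 (knockout replicate 3), 365 (knockout replicate 4), 376 (knockout replicate 2) or 383 (wild-type replicate 4), and no call changed sign.

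Among the 12 strongest rises, after Hbegf (18:36504927-36515805; log2 fold change 1.58 ± 0.11 SE) came Bmp10, a bone morphogenetic protein, which went from 0.897 to 4.2 FPKM (1.44 ± 0.12, adjusted p = 2.02e-04). Lipg (18:74939322-74961263) followed at 1.35 ± 0.10 and Syna at 1.05 ± 0.12. Crlf1, a cytokine receptor-like factor, rose from 2.15 to 5.42 FPKM (1.0, adjusted p = 0.00736), and Tgfa, which encodes another ligand of the EGF receptor, from 4.95 to 9.20 FPKM (0.80, adjusted p = 0.0163). Lrp8, a receptor of the LDL receptor family, rose from 6.65 to 12.1 FPKM (0.79, adjusted p = 0.0019). The other 5 were Lonrf3 (0.92), Nqo1 (0.83, an NADPH-using quinone reductase), Cpne5 (0.80), Itih5 (0.79) and Slc26a7 (0.77), with adjusted p from 2.02e-04 to 0.00293. Measured in FPKM, the largest rise among called genes was that of Ctsj, a placental cathepsin, from 2038 ± 427 to 2971 ± 104 (n = 5, limma, adjusted p = 0.0168). Lipg, Tpm4 (204 to 249 FPKM; a call lost in 9 settings, nearly all with 1 library left out), Anxa5 (143 to 174 FPKM) and Cd9 (95.6 to 123 FPKM) completed the 5 largest. With the 7 deeper libraries alone, the calls of Crlf1, Tgfa, Ctsj, Tpm4, Anxa5 and Cd9 were lost. The rest of the 12 strongest rises kept theirs.

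The 12 strongest falls were of genes with varied functions. Below Zfp36l3 and Tfrc (16:32608896-32632794, −2.84 ± 0.35) stood a predicted gene at −1.87. Next came Rpl39, a ribosomal protein gene that fell from 27.8 to 9.84 FPKM (−1.36, adjusted p = 0.0118). Mt2, a metallothionein, fell from 80.2 ± 27.4 to 32.7 ± 12.5 FPKM (n = 5, −1.28, limma, adjusted p = 0.0144). Rpl37a (−1.26) and Rpl37 (−1.19) fell too, but both have near-identical copies elsewhere and are uncertain. Atp5e, a subunit of ATP synthase, fell from 19 to 8.05 FPKM (−1.11, adjusted p = 0.0132), and Romo1 from 4.40 to 1.54 FPKM (−1.05, adjusted p = 0.012). S100a8, a calcium-binding protein of neutrophils, fell from 18.5 to 7.35 FPKM (−1.21, adjusted p = 0.00464). By contrast, S100a9 of the macrophage and granulocyte list had 1.15 and 1.77 FPKM (0.38, adjusted p = 0.13). Slc27a3, a fatty acid transport protein, fell from 6.94 to 2.62 FPKM (−1.13, adjusted p = 0.00272), and Palm3 from 5.14 to 1.95 FPKM (−1.02, adjusted p = 0.00363). The predicted gene completed the 12. In FPKM, Tfrc fell most among called genes, followed by Creg1 (872 to 704) and Rpl41 (172 to 97.0, uncertain because of near-identical copies). Peg10 (309 to 247, near copies not searched for) and Mt2 came after these. The calls of Creg1 and Rpl41 were lost in 8 and 10 settings, most of them with 1 library left out. With the 7 deeper libraries alone, Rpl39, Mt2, Rpl37a, Rpl37, Atp5e and S100a8 lost their calls as well. Tfrc, Romo1, Slc27a3 and Palm3 kept theirs. Among the 73 tested genes with transcripts under 500 nucleotides, 14 were lower and 3 higher, with a median log2 fold change of −0.24. Their mean centred log2 level was 0.247, 0.024, 0.21, 0.228 and 0.016 in wild-type replicates 1 to 5, and 0.083, −0.105, −0.31, −0.261 and −0.133 in knockout replicates 1 to 5 (exact permutation test, two-sided, p = 0.0238; 0.149 adjusted over the 25 scores compared in this way).

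**Figure D2:**
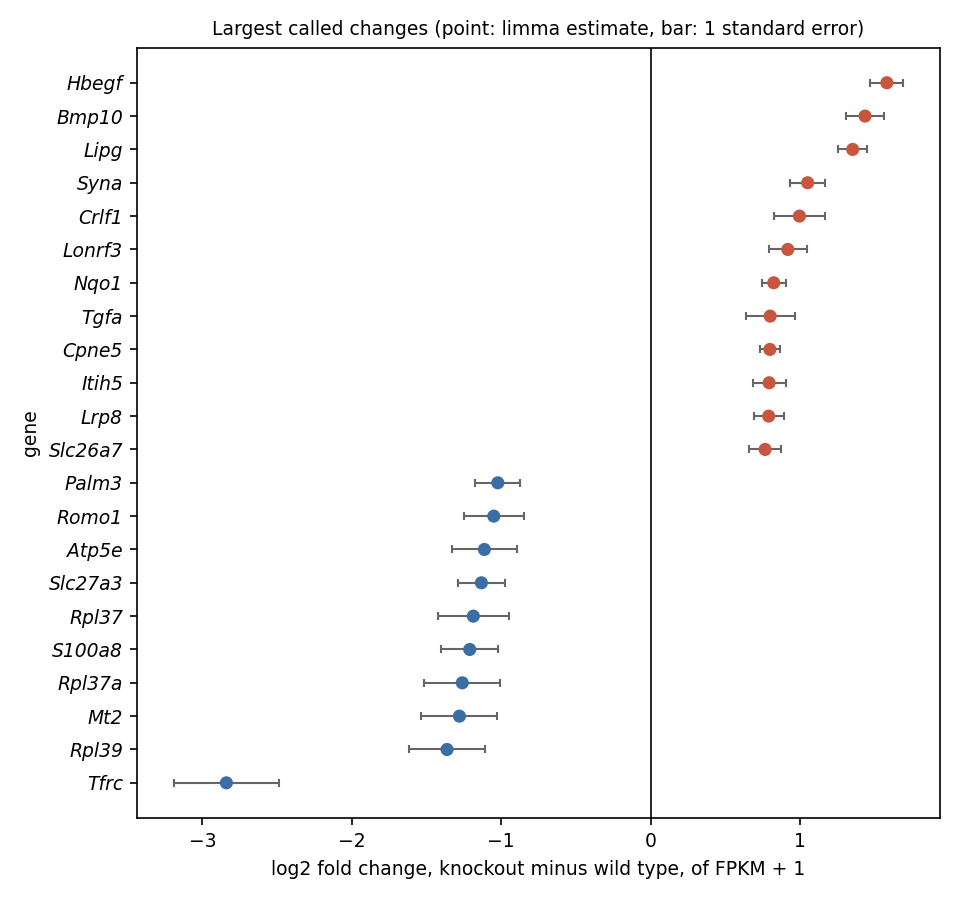
Log2 fold change of FPKM + 1, knockout minus wild type (x axis), of 22 called genes, as points with SE bars from limma, n = 5 per group. Tfrc lies at −2.84 and Hbegf at 1.58. The targeted gene Zfp36l3 (−5.20, listed at 0 in all knockouts) and a predicted gene at −1.87 are not drawn.

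Among genes of iron handling, Tfrc alone was called. It was the only one of the 19 tested members of the list for iron uptake, storage and export to pass, 1 lower and 0 higher, and the same count was reached when adjusted over the list alone. Log2 fold changes of the other 18 ran from −0.67 to 0.32, with a smallest adjusted p of 0.179. Fth1, a ferritin subunit, had 138 FPKM in wild type and 140 in knockout (0.01, adjusted p = 0.915), and Slc40a1, the iron exporter ferroportin, 58.9 and 63.3 FPKM (0.11, adjusted p = 0.544). The list as a whole was not called (camera, down, adjusted p = 0.581). Trf, the transferrin gene, had 112 ± 128 FPKM in wild type against 50.7 ± 16.5 in knockout (n = 5; limma, adjusted p = 0.461). Its spread came from wild-type replicate 3 at 339 FPKM, the library with the highest level of yolk sac endoderm markers, and Trf shares sequence with another gene and is uncertain. Of 9 tested genes whose mRNA carries an iron-responsive element, Tfrc alone passed; adjusted over the list alone, Tfrc was lower and 2 were higher. Aco2, the mitochondrial aconitase, had 26.9 and 31.4 FPKM (0.22, adjusted p = 0.0655). In that list the median was 0.04, the mean −0.27 and the direction of the test up (camera, adjusted p = 0.581). Both iron lists were fixed knowing that the published study of this knockout had drawn attention to placental iron, so they are not independent evidence of its direction.

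Reported AU-rich targets of TTP-family proteins stood higher in knockout placentas as a list. Among 19 tested members, 15 had positive fold changes and 2 were called, both higher. Zfp36, Zfp36l1 and Zfp36l2, of the TTP family itself, belong to this list and were among the 15, uncalled. Cxcl1, a neutrophil chemokine, rose from 2.41 to 4.64 FPKM (log2 fold change 0.75, adjusted p = 0.037), and Ldlr, the low density lipoprotein receptor, from 6.33 to 9.73 FPKM (0.56, adjusted p = 0.0147). Hif1a, a hypoxia-responsive transcription factor, had 25.1 and 32.3 FPKM (0.35, adjusted p = 0.0576). The uncalled members lay between −0.13 and 0.35, and the call of Cxcl1 was lost in 9 of the settings tried, most of them with 1 library left out. Adjusted over the list alone, 3 were higher and 0 lower. The list was called higher by camera with a preset correlation (adjusted p = 0.00245). It was not called at adjusted p = 0.361 with an estimated correlation. Its mean level was higher in each knockout library than in each wild-type library. At the closest, knockout replicate 5 stood at 0.024 and wild-type replicate 4 at 0.019. The exact permutation test, two-sided, gave p = 0.00794, the smallest that 5 against 5 allows. Adjusted over the 25 scores compared in this way, it was 0.0992. With the 7 deeper libraries alone, camera's adjusted p for the list was 0.00227.

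The core of the TTP-family binding site, TATTTAT, was more frequent in the 3' UTRs of genes that rose. Of 302 called-higher genes with an annotated 3' UTR, 189 (62.6%) held at least 1 TATTTAT, against 2840 of 9258 uncalled genes (30.7%; odds ratio 3.78, Fisher's exact test, two-sided, p = 4.92e-29). Genes that rose had longer 3' UTRs, with a median of 1609 nucleotides against 1151 in uncalled genes, and the odds ratio with log2 length as a covariate was 3.69 (95% interval 2.83 to 4.81). Genes that fell held the motif less often than uncalled genes, in 36 of 278 cases (12.9%; length-adjusted odds ratio 0.36, 0.25 to 0.52). None of 20 shuffled heptamers of the same bases reached the odds ratio of TATTTAT in genes that rose (range 1.03 to 3.27), and the highest, ATTTATT, overlaps TATTTAT in a neighbouring frame. In genes that fell, TATTTAT lay below 19 of the 20 shuffled heptamers, which ranged from 0.28 to 1.05 with a median of 0.666. With the 7 deeper libraries the length-adjusted odds ratio was 5.39 for genes that rose (42 of 60) and 0.54 (0.28 to 1.02) for genes that fell. Genes are not independent replicates, so these tests describe the gene groups.

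Single 3' UTRs differed in the motifs they held. In Hbegf, the annotated 3' UTR held 2 sites, at 18:36505752-36505758 within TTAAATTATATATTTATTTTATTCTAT and at 18:36504967-36504973, both on the minus strand. Lipg also held 2, at 18:74939528-74939534 and 18:74939458-74939464, and Cxcl1 held 6, of which 4 lay between 5:90892610 and 5:90892632. Bmp10 and Ldlr held 3 sites each, and Tgfa, Itih5 and Slc26a7 held 2 each. No TATTTAT was found in the annotated 3' UTRs searched for Syna, Crlf1, Lonrf3, Nqo1 or Cpne5, all of which rose. These 3' UTRs had 94, 247, 422, 594 and 3466 nucleotides, so the shorter ones offered little sequence to search. Lrp8, which also rose, held none in the 35-nucleotide 3' UTR of the transcript searched for positions, and 2 in its longest annotated 3' UTR of 1588 nucleotides. Tfrc, which fell, held 2, at 16:32631148-32631154 and 16:32631159-32631165. Rpl39, Mt2, Rpl37a, Rpl37, Atp5e, Romo1, S100a8, Slc27a3 and Palm3, which also fell, held none in 3' UTRs of 68 to 504 nucleotides.

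**Figure D3:**
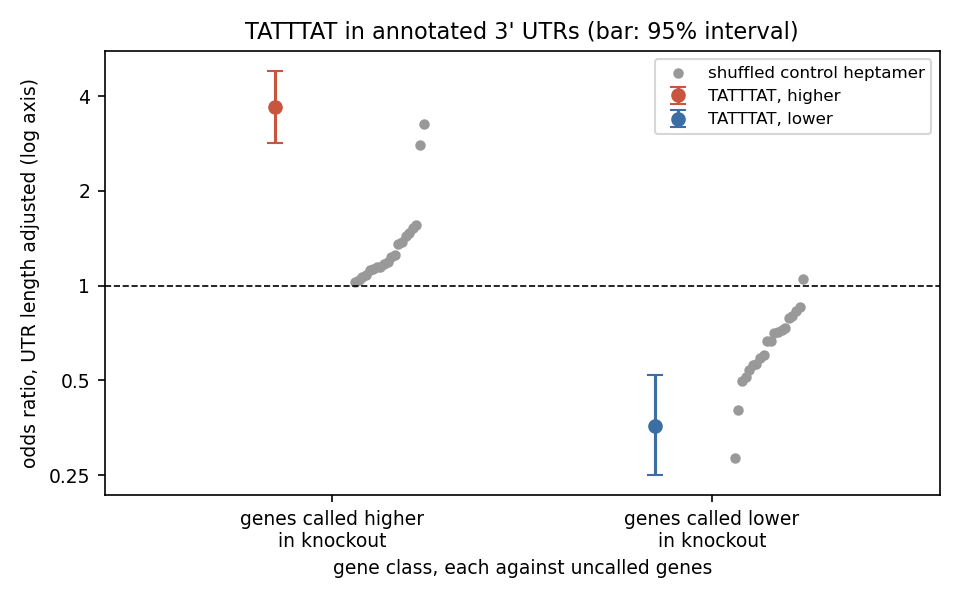
Odds ratio of TATTTAT in 3' UTRs of called against uncalled genes, with log2 UTR length as a covariate and 95% intervals (log axis), beside 20 shuffled heptamers. The motif stands at 3.69 for genes higher in knockout placentas, above the range of 1.03 to 3.27 of the shuffled heptamers, and at 0.36 for genes that were lower.

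In the labyrinth list, both syncytin genes changed, in opposite directions. Syna rose, while Synb, the gene of syncytin-B, fell from 40.2 ± 6.65 to 25.5 ± 1.88 FPKM (n = 5; −0.62; limma, adjusted p = 0.0067), with the reservation that Synb shares sequence with another gene. Gcm1, a transcription factor of syncytiotrophoblast formation, fell from 9.29 to 5.56 FPKM (−0.63, adjusted p = 0.00665). Snap91, chosen after its values were seen because it was the fifth called member, rose from 5.27 to 7.52 FPKM (0.45, adjusted p = 0.0205). With Tfrc, 3 of the 20 tested syncytiotrophoblast and labyrinth genes were lower and 2 higher, or 4 lower and 2 higher adjusted over the list alone, and the list was not called (camera, down, adjusted p = 0.581). Spongiotrophoblast and glycogen trophoblast genes gave 1 call in 24, also 1 adjusted over the list alone. It was Egfr, the EGF receptor, which fell from 3.19 to 2.09 FPKM (−0.43, adjusted p = 0.0257), a call lost in 6 settings, mostly by leaving out 1 library. Aldh1a3 in the same list had 29.2 and 46.4 FPKM (adjusted p = 0.128), and the list was not called (camera, up, adjusted p = 0.581).

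Giant cell and prolactin genes stood higher as lists. Of 19 trophoblast giant cell genes, 3 rose and 0 fell, also when adjusted over the list alone: Ctsj, Prl4a1 (29.3 to 46.9 FPKM, 0.66, adjusted p = 0.00301) and Prl3d3 (0.993 to 1.57 FPKM, 0.36, adjusted p = 0.037, uncertain because of a near-identical copy, and a call lost in 10 settings). The list was called higher by camera (adjusted p = 0.00523) but not at adjusted p = 0.831 with an estimated correlation, and with the 7 deeper libraries its adjusted p was 0.0531. The exact permutation p of its mean level was 0.0635 (0.227 adjusted over the 25 scores). In the placental prolactin family, which shares members with that list, 20 of 24 genes had positive fold changes. Of these, Prl4a1 and Prl3d3 passed, 2 higher and 0 lower also when adjusted over the list alone. Camera called the family higher (adjusted p = 0.00245), though not at adjusted p = 0.831 with an estimated correlation, and gave 0.0531 with the 7 deeper libraries, and the exact permutation p of its mean level was 0.103 (0.309 adjusted). Wild-type replicate 3, the library rich in yolk sac markers, had the lowest mean centred log2 level of the prolactin family at −0.43, and its spongiotrophoblast level of −0.26 lay below the −0.01 to 0.08 of the other wild-type libraries.

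Red cell genes stood lower in knockout placentas, with 1 knockout library apart. Gata1, the erythroid transcription factor, fell from 2.62 to 1.28 FPKM (−0.66, adjusted p = 0.0018) and was the only 1 of 17 erythroid genes called, also when adjusted over the list alone. Negative fold changes were found in 14 of the 17. Hba-a1, an adult alpha globin with a near-identical copy, had 2715 and 2045 FPKM (adjusted p = 0.139), and Hba-x, an embryonic globin, 46.1 and 25.9 FPKM (adjusted p = 0.122). The list was called lower by camera (adjusted p = 0.0174), but not at adjusted p = 0.831 with an estimated correlation, nor with the 7 deeper libraries (0.0531), after a correction for transcript length and GC content (0.17), without wild-type replicate 5 (0.183) or without knockout replicate 1 (0.104). The exact permutation p of its mean level was 0.111 (0.309 adjusted over the 25 scores). The mean centred log2 level of the list was 0.43 in knockout replicate 5 and −0.38 to −0.20 in the other 4 knockouts, against −0.02 to 0.45 in wild type. Knockout replicate 5 was also the knockout library with the highest Tfrc level, 95.7 FPKM against 26.6 ± 4.98 in the other 4.

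Maternal decidua genes were called higher as a list although none of its members passed. Of 22 tested, 18 had positive fold changes, 0 were called over all genes and 0 adjusted over the list alone. Camera gave an adjusted p of 0.0497, against adjusted p = 0.831 with an estimated correlation, 0.223 with the 7 deeper libraries and 0.0525 after the correction for length and GC content. Its mean level had an exact permutation p of 0.31 (0.569 adjusted over the 25 scores). The mean centred log2 level was 0.553 and 0.814 in knockout replicates 1 and 2 and −0.512 to 0.066 in the other 8 libraries, and without replicate 1 or replicate 2 of the knockouts or without wild-type replicate 1 or 5 camera's adjusted p was 0.132, 0.4, 0.0669 or 0.359. Angpt2, an angiopoietin, had 7.44 and 10.7 FPKM (adjusted p = 0.0593), and Prl8a2, a decidual prolactin, 138 and 203 FPKM (adjusted p = 0.355). Uterine natural killer cell genes, of which 8 were tested and 0 passed on either adjustment, peaked in the same libraries, at 1.25 and 1.5 (camera, up, adjusted p = 0.477). Yolk sac endoderm genes had negative fold changes in 18 of 20 cases, with 0 calls on either adjustment (camera, down, adjusted p = 0.147). Their mean centred log2 level reached 2.88 in wild-type replicate 3 and lay between −1.05 and 0.90 elsewhere.

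**Figure D4:**
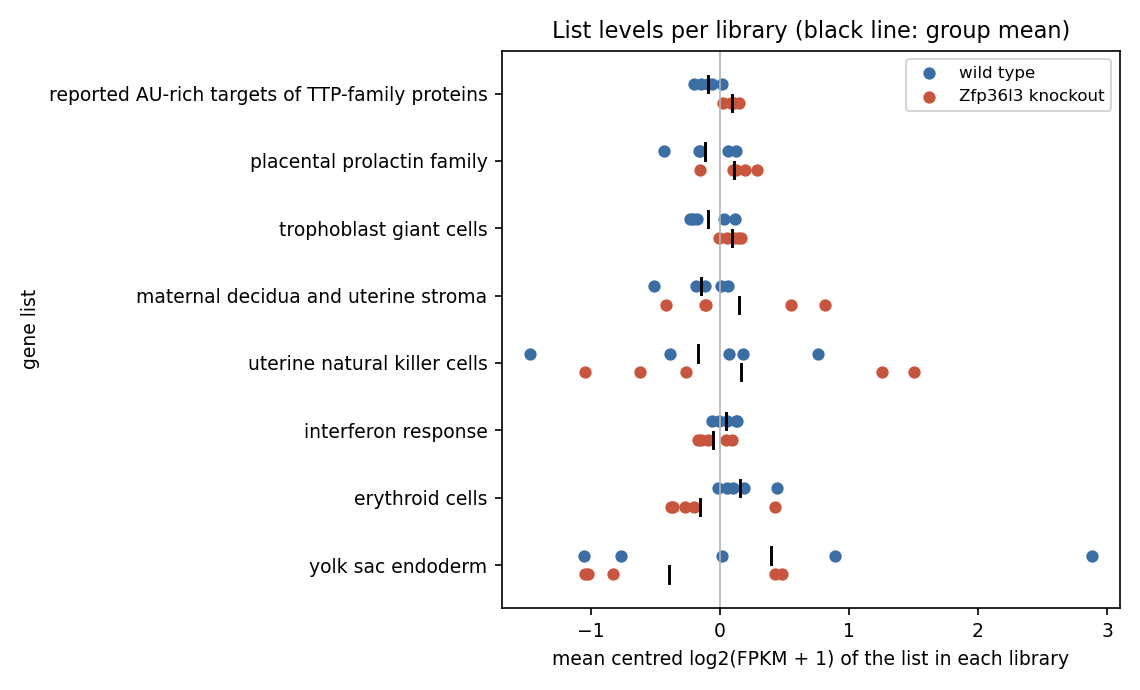
Mean centred log2(FPKM + 1) of 8 gene lists (y axis) in each of the 10 libraries, 1 point per library, wild type and knockout apart. Yolk sac endoderm genes reach 2.88 in wild-type replicate 3, and decidual genes 0.553 and 0.814 in knockout replicates 1 and 2.

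The list of interferon response genes stood slightly lower in knockout placentas. Of 21 tested, 5 fell and 0 rose, or 7 lower and 0 higher adjusted over the list alone. Bst2, the antiviral tetherin, fell from 75.1 to 53.7 FPKM (−0.48, adjusted p = 0.0211), and Isg15, a ubiquitin-like modifier, from 15.4 to 11 FPKM (−0.46, adjusted p = 0.0178). Ifih1 (−0.31), Usp18 (−0.27) and Irf9 (−0.23; chosen after its values were seen) fell by less, with adjusted p of 0.0109 to 0.0422. The call of Irf9 was lost in 12 settings, and those of Bst2 and Isg15 in 3, namely without wild-type replicate 2 or knockout replicate 3 and with the 7 deeper libraries, where those of Ifih1 and Usp18 were lost too. Camera called the list lower (adjusted p = 0.031; 0.0357 with the 7 deeper libraries), but not at adjusted p = 0.831 with an estimated correlation, and not without wild-type replicate 1 (0.108), knockout replicate 3 (0.0647) or knockout replicate 5 (0.11). Its mean level had an exact permutation p of 0.151 (0.364 adjusted over the 25 scores). Macrophage and granulocyte genes, of which S100a8 alone of 11 was called, had a median of 0.35 and were not called as a list (camera, up, adjusted p = 0.158). The list of macrophages and granulocytes was called higher with the 7 deeper libraries (0.0168), after the correction for length and GC content (0.0334), without transcripts under 500 nucleotides (0.0237), with no filter on low values (0.00162) and without knockout replicate 3 (0.036), but not with an estimated correlation (adjusted p = 0.831). Adjusted over the list alone, 3 of the 11 were higher and 2 lower.

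Transporters and metabolic genes moved in both directions. Of 31 tested genes for amino acid, glucose and lipid transport, 7 rose and 2 fell, or 7 higher and 4 lower adjusted over the list alone. Slc7a7, a subunit of a cationic amino acid exchanger, rose from 2.23 to 3.83 FPKM (0.58, adjusted p = 0.00411), as did Lipg and Ldlr. Slc38a2 (45.1 to 58.4 FPKM), Slc7a1 (38.7 to 47.5 FPKM), Lpl (3.16 to 4.53 FPKM) and Mfsd2a (18.2 to 24.6 FPKM), chosen after their values were seen, rose as well (0.29 to 0.41). The calls of Slc7a1, Slc38a2 and Mfsd2a were lost in 13, 9 and 8 settings, most of them with 1 library left out. Slc1a5, a glutamine transporter, fell from 12 to 7.83 FPKM (−0.56, adjusted p = 0.00165), and Slc7a2, a cationic amino acid transporter, from 4.59 to 3.03 FPKM (−0.47, adjusted p = 0.00433). The list's median was −0.07, its mean 0.01 and the direction of its test up (camera, adjusted p = 0.665). Among 22 cholesterol synthesis and SREBP2 target genes Ldlr rose and Dhcr24 fell (26.2 to 20.6 FPKM, −0.33, adjusted p = 0.0418, a call lost in 11 settings), the same 2 counts adjusted over the list alone (camera, down, adjusted p = 0.457). In the respiratory chain list, Cox7c alone of 26 passed (18.1 to 12.4 FPKM, −0.51, adjusted p = 0.00703; uncertain because of near-identical copies), also when adjusted over the list alone (camera, down, adjusted p = 0.345). Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, was the only 1 of 24 unfolded protein and stress response genes to pass on either adjustment (35.4 to 27.0 FPKM, −0.39, adjusted p = 0.0366, a call lost in 10 settings), and that list was not called (camera, down, adjusted p = 0.68).

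Imprinted genes likewise split. Slc22a3, an organic cation transporter, fell from 16.7 to 9.11 FPKM (−0.81, adjusted p = 0.00147), and Peg10, a retrotransposon-derived placental gene, from 309 to 247 FPKM (−0.32, adjusted p = 0.039), a call lost in 13 settings, most of them with 1 library left out. Sgce rose from 6.80 to 9.01 FPKM (0.36, adjusted p = 0.00916), and Snrpn from 4.81 to 8.03 FPKM (0.65, adjusted p = 0.0119), uncertain because 24.3% of its 50-base words occur in transcripts of a predicted gene. These were the 4 called of 33 tested, or 2 higher and 3 lower adjusted over the list alone (camera, down, adjusted p = 0.905). Pdgfrb, a pericyte receptor, rose from 6.26 to 8.55 FPKM (0.39, adjusted p = 0.0119) as the only call on either adjustment among 14 mesenchyme and pericyte genes (camera, up, adjusted p = 0.358). No gene passed on either adjustment among 19 of the fetal endothelium (median −0.01, mean −0.01, camera up, adjusted p = 0.679), 21 of the hypoxia response (camera, up, 0.346), 19 of cell division (camera, down, 0.259) or 4 on the Y chromosome (camera, down, 0.64). The uncalled log2 fold changes were −0.33 to 0.28 in endothelium, −0.25 to 0.31 in hypoxia response and −0.26 to 0.24 in cell division. Y-linked genes were expressed in all 10 libraries. No list was called with an estimated correlation.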

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

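In this part, the tests of transcript length bias, of lower depth, of a mislabelled sample and of fewer erythroid cells as the source of the Tfrc fall were chosen after the results were seen. The correction for length and GC content was also added then.

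Single libraries lay far from the other 4 of their group in 19 of 224 groups of 5 values examined, where chance alone sets about 1 in 20 groups apart.

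Knockout replicate 4 stood apart in several genes. It had 2.573 FPKM of Bmp10 against 4.524 to 4.762 in the other knockouts, 220.855 of Peg10 against 251.29 to 257.772, 6.023 of Snap91 against 7.655 to 8.129, 6.422 of Snrpn against 8.154 to 8.815 and 6.72 of Snurf against 8.197 to 8.702. Its estimated depth, 45.7 M reads, lay below the 60.2 to 64.5 M of the other knockouts. In knockout replicate 1, Cxx1c had 9.66 FPKM against 6.908 to 7.272 and Romo1 2.368 against 1.174 to 1.501. Knockout replicate 2 had 2.573 FPKM of Ifih1 against 2.154 to 2.232, and knockout replicate 3 had 5.109 of Ppp1r9a against 4.003 to 4.318. Among wild-type libraries, replicate 4 had 2.099 FPKM of Gata1 against 2.615 to 2.796, and replicate 5 had 211.182 of Prl8a2 against 110.649 to 125.95. Wild-type replicate 3 had 37.89 FPKM of Spp2, a secreted phosphoprotein of the yolk sac list, against 0.374 to 5.32, 339.144 of Trf against 38.187 to 80.745, and a spongiotrophoblast and glycogen trophoblast level of −0.258 against −0.005 to 0.078. Knockout replicate 5 had 6.637 FPKM of Srxn1 against 4.894 to 5.126, 44.091 of Hba-x against 17.985 to 24.975, 95.72 of Tfrc against 22.399 to 32.537, and an erythroid level of 0.43 against −0.381 to −0.197.

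The Tfrc level of knockout replicate 5, and the fall of Tfrc as a whole, could come from red cell content, since erythroid precursors use the transferrin receptor. A mislabelled sample is argued against, because Zfp36l3 was listed at 0 FPKM in that library. More erythroid cells as the whole source of its Tfrc level is argued against too: the 17 erythroid markers exceeded the other 4 knockouts by a median of 0.797 (upper quartile 0.92) on the log2 scale, and Tfrc by 1.83. For the fall between genotypes, the lower quartile of the markers' log2 fold changes was −0.446 and Tfrc's −2.84, which argues against fewer erythroid cells as the whole cause. A part from erythroid cells stays open, and so do a change in erythroid stage and an effect of the lost protein on Tfrc mRNA in trophoblast, neither of which was tested.

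Short transcripts tended to be lower in knockout libraries, with 14 called lower and 3 higher of 73 under 500 nucleotides, but the exact permutation p of their mean level was 0.0238 before adjustment and 0.149 after, and knockout replicate 1 (0.083) lay above wild-type replicates 2 (0.024) and 5 (0.016). A fall of ribosomal protein genes by an equal amount at all lengths is argued against. The 57 of them with transcripts of 600 nucleotides or more had a median log2 fold change of −0.058 (95% interval −0.131 to −0.031). Of these, 4 were called lower and 0 higher. Genes of that length outside the ribosomal protein and respiratory chain families had −0.016 (−0.02 to −0.013). A smaller fall of the family, or one of its short members alone, stays open. A length bias of the libraries may account for part of the pattern. The 49 short genes outside the ribosomal protein and respiratory chain families also had a median of −0.211 (−0.362 to −0.032). The 95% intervals in this paragraph came from resampling genes, which are not independent replicates, and hold no spread between placentas. The correction for length moved the median of transcripts under 500 nucleotides from −0.244 to −0.122 and left 13 of the 14 lower calls. It moved the median of the 49 to −0.077. The 13 ribosomal protein genes under 500 nucleotides had a median of −0.473 (−0.934 to −0.397), and of −0.381 after the correction. The test of depth did not decide, because the 2 deeper wild-type libraries stood at 0.024 and 0.247. Of these, 1 lay within and 1 above the knockout range of −0.31 to 0.083. The shallower wild-type libraries stood at 0.21, 0.228 and 0.016, and so did not lie apart from the deeper ones. A biological fall of small mRNAs stays open as well, and was not tested separately from length.

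Of 6 tested genes next to Zfp36l3 on the X chromosome, within 200 kb and noticed after their values were seen, 3 were called higher in knockout placentas and 3 were not (adjusted p 0.258 to 0.547). The 3 called, none of which kept its call with the 7 deeper libraries (adjusted p 0.0573 to 0.124), were Xlr, 724 nucleotides away (0.989 to 2.05 FPKM, log2 fold change 0.62, limma adjusted p = 0.00593), Cxx1c (4.75 to 7.6 FPKM, 0.58, adjusted p = 0.01) and AW822252 (0.969 to 1.58 FPKM, 0.39, adjusted p = 0.0153). Such clusters were rare elsewhere, as 0.262% of windows of 6 neighbouring genes (26 of 9912) held as many. That share makes no allowance for these genes having been noticed first, so chance clustering is not excluded by it. Cxx1a, Cxx1b and Cxx1c are near copies and so may not be independent. Between 200 kb and 10 Mb, 2.94% were called (1 of 34, exact upper 95% bound 15.3%), against 5.88% of other genes. A wide stretch of another strain's DNA is argued against only if it would raise that share to 17.6%, 3 times that of other genes. A smaller rise cannot be judged from so few genes, and the strains were not given. An effect of the altered allele on its neighbours, or passenger DNA in a short stretch or with a weaker effect, remains a candidate explanation.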

How the results depend on the processing

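The correction for length and GC content, the settings with 7 deeper libraries or other wild-type pairs, the mean over accessions and the omission of short transcripts were chosen after seeing the data; the rest were planned. No called gene changed sign under any setting, apart from the other wild-type pairs, where signs were not compared. Against 595 genes called (305 higher, 290 lower), a minimum of 5 FPKM gave 368 (198 and 170) by testing fewer genes, array weights 2606 (1044 and 1562), the length and GC correction 1299 (592 and 707), and the 7 deeper libraries 136 (61 and 75). The other 9 pairs of wild-type libraries against the 5 knockouts gave a median of 52 (27 and 25; totals 10 to 176), so fewer libraries are enough for that drop. The exact rank-sum test gave 0 after adjustment and 1730 at an unadjusted p below 0.05 (2182 by limma), because its smallest possible p of 0.00794, reached by 809 genes, came to 0.0989 after adjustment. Leaving out 1 library gave 282 to 711 (higher 173 to 338, lower 109 to 373); counts moved over 1.5 times without wild-type replicate 2 (282), wild-type replicate 4 (383) and knockout replicates 2 (376), 3 (290) and 4 (365), and those lower also without wild-type replicates 1 (185) and 3 (184). Lists called higher, 4, came to 2 with the 7 deeper libraries, 0 with an estimated correlation and 1 with fry, and to 3 to 5 without 1 library. Those 2 were the AU-rich targets and the macrophage and granulocyte list, which the main test did not call. The giant cell, prolactin and decidua lists were lost there. After the length and GC correction the count stayed 4, with macrophages and granulocytes in place of decidua. Lists called lower, 2, came to 1 with array weights, the Y-linked covariate, the length and GC correction and the 7 deeper libraries, 0 with an estimated correlation, and 1 to 3 without 1 library (1 without knockout replicate 1 or 3; 3 without wild-type replicate 1 or knockout replicate 4 or 5). Yolk sac endoderm joined them with no filter and without wild-type replicate 1 or 5 or knockout replicate 4 or 5, and cell division without wild-type replicate 1 or knockout replicate 5; with no filter and without wild-type replicate 5 the count stayed 2 because the erythroid list was lost. With fry, neither of the 2 was called, and the 1 called lower was the TTP family, which holds the deleted gene. The odds ratio of TATTTAT, 3.69 in genes that rose and 0.36 in genes that fell, compares with shuffled medians of 1.207 and 0.666, and in genes that fell became 0.54 (95% interval 0.28 to 1.02) with the 7 deeper libraries. Other settings kept these results within 1.5 times or on their side of the threshold, and unless stated the cause was not tested. Calls of single genes were followed through all settings but the exact rank-sum test, which called 0, and the other wild-type pairs. Of 65 called genes named, 39 lost their call with the 7 deeper libraries. In every one of the settings followed that tested them, 24 kept theirs. Among them were Zfp36l3 (−8.48 to −3.03), Tfrc (−3.21 to −2.65), Hbegf (1.31 to 1.66), Lipg (1.22 to 1.41), Syna (0.90 to 1.12), Synb (−0.81 to −0.56) and Bmp10 (0.64 to 2.09). Peg10 and Slc7a1 lost it in 13 settings, Irf9 in 12, Dhcr24 in 11, and Rpl41, Prl3d3 and Sdf2l1 in 10. Depth limits low genes most, as 3 of 5 wild-type libraries were estimated at 31.0 to 33.9 M reads.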

Other observations

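The genes in the next 2 paragraphs were chosen after their values were seen, as were the tests of the hypothesis on AU-rich elements in the last. Hbegf and Tgfa, which encode ligands of the EGF receptor, rose by 1.58 and 0.80 on the log2 scale, while Egfr fell from 3.19 ± 0.58 to 2.09 ± 0.26 FPKM (n = 5; limma, adjusted p = 0.0257), a call lost in 6 settings. No list of the EGF pathway was tested. Erbb3, a related receptor, had 1.70 FPKM in wild type and 1.56 in knockout (adjusted p = 0.724), and Errfi1, a feedback inhibitor induced by EGF receptor signalling, 35.8 and 41.5 FPKM (adjusted p = 0.478). Both metallothioneins tested were lower: beside Mt2, Mt1 fell from 89.9 ± 28.7 to 48.0 ± 12.6 FPKM (−0.87; n = 5; limma, adjusted p = 0.0328), with groups that overlapped and a call that was lost in 9 settings. Their transcripts are longer than the 500 nucleotides that bound the class of short genes described above.

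Nqo1 rose together with Srxn1, a sulfiredoxin that like Nqo1 is a target of the oxidative stress regulator NRF2 (3.87 to 5.31 FPKM, 0.37, adjusted p = 0.022). Of 4 other NRF2 targets looked up, none was called. Gclm had 8.97 and 10.02 FPKM (adjusted p = 0.259), Gclc 3.88 and 4.48 (0.214), Txnrd1 2.62 and 2.98 (0.179) and Hmox1 42.6 and 45.9 (0.588). Around Peg10, which fell, the neighbouring imprinted gene Sgce rose, and Casd1 (7.93 to 9.85 FPKM, 0.29, adjusted p = 0.0643) and Ppp1r9a (3.54 to 4.38 FPKM, 0.25, adjusted p = 0.0956) had positive, uncalled fold changes. Snurf, whose annotated gene overlaps Snrpn, rose from 4.62 to 8.02 FPKM (0.70, adjusted p = 0.00955). Firre, an X-linked long noncoding RNA, was the 1 called gene between 200 kb and 10 Mb from Zfp36l3 and fell from 7.07 to 5.15 FPKM (−0.39, adjusted p = 0.0128).

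The counts of calls were compared with those of other splits of the 10 libraries. In 1 of 100 splits of the libraries into 5 and 5, the real one, 595 genes were called, and the highest count of any other split was 1. The same held for genes higher, with 305 in the real split, 1 split of 100 reaching it and at most 1 gene in any other, and for genes lower, with 290, 1 of 100 and at most 1. A random division of the libraries is thus argued against as the source of these counts. The splits cannot tell genotype from any other difference between the groups, such as depth or litter, and litter was not given.

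One hypothesis is that part of the rise in transcripts is direct loss of TTP-family decay in trophoblast. The odds ratio of TATTTAT in genes that rose was 3.69 (2.83 to 4.81). Base composition of the UTRs is argued against as its source, since the highest of the 18 shuffled heptamers outside the motif's frame reached 1.562, below that interval. The odds ratio was 5.39 with the 7 deeper libraries and 3.02 after the length and GC correction, which is consistent with that hypothesis without showing binding or decay of any transcript. Syna, Crlf1, Lonrf3, Nqo1 and Cpne5 rose with no TATTTAT in the 3' UTRs searched and Tfrc fell with 2, so the motif alone does not predict direction. A test of mRNA half-lives or of binding would be needed, and neither is among the data used here.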
